A study of Homo sapiens with 12 samples.

How the data were processed

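The series holds 12 RNA-seq libraries of GM21 human skin fibroblasts carrying oncogenic H-RAS, which the labels divide into 6 groups of 2: the non-targeting vector pLKO and the POU2F2 hairpins sh324 and sh325, each at day 14 and day 27. The labels give polyadenylated RNA and a library kit that marks strand. They do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between libraries, which may be technical.

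The submitters' processing notes name Bowtie2, DESeq2, MultiQC and the genome build hg19, without versions, roles or order. Bowtie2 does not split reads across introns. The counting program, its use of strand, the gene annotation, the filter and the design formula are not given in the sources used here. The analysis used a single table of 15420 genes with 12 columns of per-library values and the result columns of 1 comparison. The 12 per-library columns are named by sequencing-run codes that match no sample label, and assigning them by order or by value would have been a guess. They were used in no step, so depth per library, replicate spread and the level of POU2F2 per library were not analysed here.

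The signal column used is the mean normalized count per gene, which the authors deposited under the header name baseMean, and which libraries it averages is not stated. The log2 fold change and its standard error, also on the log2 scale, are those the authors deposited for a comparison whose groups the file does not name. The test score deposited by the authors equals the log2 fold change divided by its standard error within 2.44e-07. The p-value the authors deposited equals the two-sided normal p of that score within 5.00e-08, and the adjusted p-value in the authors' deposited table corresponds to about 19220 tests, more than the genes listed. The smallest listed mean is 7.45 normalized counts in the authors' deposited table. No fold change, standard error or p-value of single genes was refitted from libraries.

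Because the groups are unnamed, positive values are described as higher in the numerator group. The tests planned before the data were examined (quasi-likelihood count tests of each hairpin and of both against pLKO per day, of day 27 against day 14, of the interaction, the overlap of hairpins and gene list tests with an estimated inter-gene correlation) all need libraries assigned to groups and were not run. A gene passed where the adjusted p-value in the authors' deposited table was under 0.05. Intervals of 95% are the log2 fold change plus and minus the normal quantile times the deposited standard error.

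Typical precision followed the level of a gene, but single genes departed from it. CXCL8 had a standard error of 0.90 at a mean of 68439 normalized counts and POU2F2 0.45 at 2853 in the authors' deposited table. The median standard error of the log2 fold change was 0.78 for 3291 genes with means under 50 normalized counts, 0.34 for 6411 genes from 50 to 500, 0.25 for 5236 genes from 500 to 5000 and 0.24 for 482 genes above, in the authors' deposited table. Over all genes it was 0.33 (quartiles 0.25 and 0.51), so that a log2 difference of about 0.92 was needed to pass at the median in the authors' deposited table. The steps were tested on simulated fold changes with these standard errors and 200 of 15420 genes changed: 36% of 100 genes changed by 1 on the log2 scale and 80% of 100 changed by 2 passed, along with 8 unchanged genes. Fewer genes were changed there than the 1865 that passed in the data, so these shares belong to a stricter cutoff. In a simulated table in which 1 of 27 lists was shifted by 1 SD of the statistic, that list passed and 0 others did. Genes were drawn independently with an SD of 1, so this cannot show how often lists of correlated genes pass wrongly.

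The genes to name were chosen by a rule written before the data were examined, adapted because the hairpins could not be compared. POU2F2, HRAS and POU2F1 were always named (POU2F3 is not among the listed genes). The 12 largest positive and 12 largest negative fold changes were taken among genes that passed and had a mean of at least 81.5 normalized counts (5 per 1000000 of the summed means). The last part named up to 4 members per list that passed, or the 2 with the highest means where none did. XIST, Y-linked genes and genes without a symbol were left out. In the list paragraphs, members that ran against their list, CDKN1A, TIMP1, IL6, CSF1R, RPL4, FOS and FOSB were named after their values were seen. Values of some list members are not reported here.

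The 27 gene lists were also fixed before the data were examined, and their members were matched by current and older symbols. Each was tested with limma 3.58.1 (R 4.3.3), function cameraPR, on the deposited score with a preset inter-gene correlation of 0.01, against all other listed genes, with Benjamini-Hochberg adjustment over the 27 lists. Of these, 17 passed, 8 on the positive and 9 on the negative side. An estimated correlation needs values per library, so 0.05 was used as a stricter preset, and 13 lists passed with it. Some genes are in more than 1 list.

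Gene types, neighbours, transcript lengths and GC content came from GENCODE 29, which is on a newer build than hg19, so no coordinates are printed. All 15420 identifiers matched, and 15413 had a length and GC content. For the closing observations, gene families of at least 5 members were formed from the letters that open a symbol, and 428 were tested with camera. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

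The alternatives tried were chosen after the data were seen: adjustment over the listed genes only, the Benjamini-Yekutieli adjustment, genes with means of at least 81.5 normalized counts only, centring at the median fold change, an empirical null (the statistic centred and scaled by its interquartile range, whose robust SD was 1.49), removal of pseudogenes, and for lists ranks, a correlation of 0.05, the level filter, the fold change in place of the score, and removal of the trend with GC content, length and mean level by splines with 5 degrees of freedom each.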

Results

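RNA was sequenced from GM21 cells, a line of human skin fibroblasts, into which an oncogenic form of the signalling GTPase H-RAS had been introduced by retrovirus. Before that step the cells received either pLKO, a lentiviral vector with a non-targeting hairpin, or 1 of 2 short hairpin RNAs (sh324 and sh325) against POU2F2, a transcription factor with a POU domain that binds the octamer motif. Oncogenic RAS drives fibroblasts into senescence, a lasting arrest with secretion of inflammatory factors, and the study asked what POU2F2 contributes to that state and to leaving it. The labels give 12 libraries, 2 for each of 3 constructs at day 14 and at day 27 after RAS. The values below come from 1 comparison the authors made and deposited for 15420 genes. Neither of its groups is named in the sources used here. The group in which a gene with a positive log2 fold change was higher is called the numerator group and the other the denominator group, and neither is assigned to a construct or a day. The hairpins against pLKO, the hairpins against each other and day 27 against day 14 were therefore not analysed here as separate comparisons.

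POU2F2 itself was lower in the numerator group, with a log2 fold change of -1.51 (SE 0.45, 95% interval -2.38 to -0.63, adjusted p = 0.011) at a mean of 2853 normalized counts in the authors' deposited table. HRAS, whose reads can come from the cell's own gene and from the introduced copy, was lower as well, with -1.11 (SE 0.23, adjusted p = 8.1e-05) in the authors' deposited table. POU2F1, the closest widely expressed relative of POU2F2, had -0.47 (SE 0.45, adjusted p = 0.64) in the authors' deposited table, and its 95% interval of -1.35 to 0.41 included 0. The list of POU factors had 3 members in the authors' deposited table, of which POU2F2 was the one that passed, over all genes and when adjusted over the list alone (limma's camera, adjusted p = 0.327). The POU2F2 difference did not pass when the test statistic was scaled to its own spread over all genes (adjusted p = 0.28) or under the Benjamini-Yekutieli adjustment (adjusted p = 0.094). The direction of that difference was not used to decide which group carried a hairpin.

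Of the genes in the authors' deposited table, 1865 (12.1%) had an adjusted p under 0.05, 1109 of them higher and 756 lower in the numerator group. At least 2-fold differences were found for 1406 of these genes, 901 positive and 505 negative, and at least 8-fold differences for 235, 135 positive and 100 negative, in the authors' deposited table. The median absolute log2 fold change among the genes that passed was 1.46 and the smallest was 0.5 in the authors' deposited table. Protein-coding genes were 1741 of those that passed, with 1065 positive, while the 124 genes of other types had 44 positive and 80 negative in the authors' deposited table. The count was 489 genes when the statistic was scaled to its own spread over all genes, and 1081 under the Benjamini-Yekutieli adjustment, which allows for dependence between tests.

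**Figure D1:**
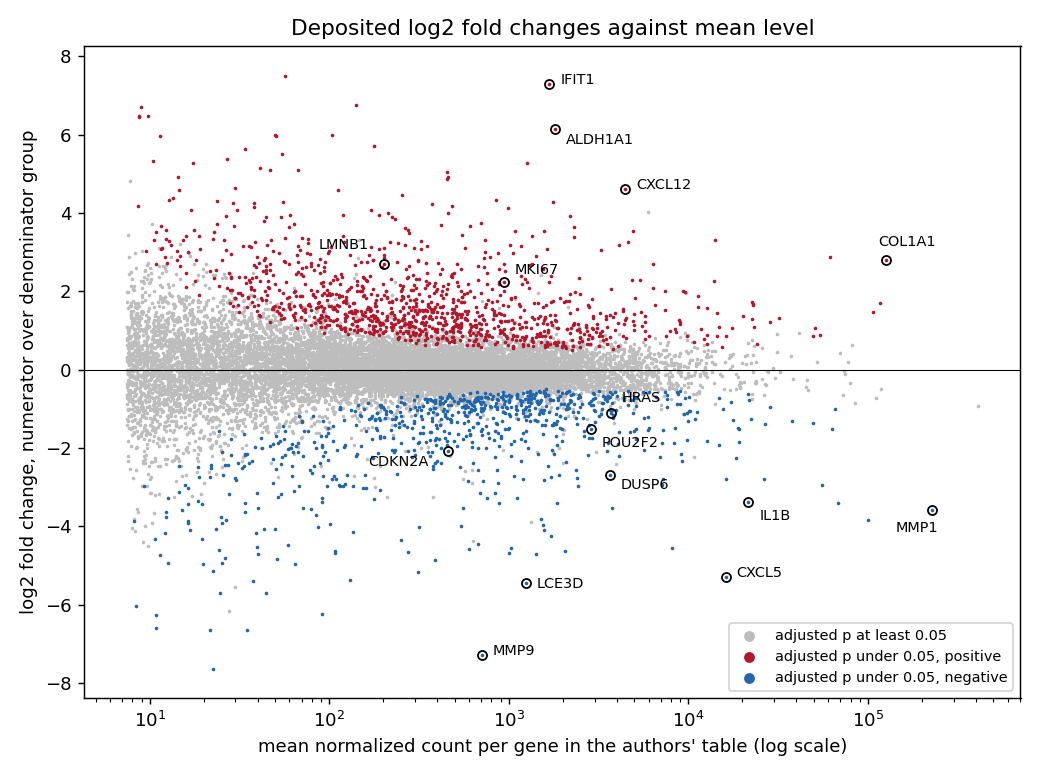
Log2 fold change of each gene (numerator over denominator group) against its mean normalized count on a log axis, both from the authors' deposited table. Each point is a gene, red where the adjusted p was under 0.05 and the gene was higher in the numerator group (1109 in the whole table), blue where it was lower (756 in the whole table) and grey otherwise, and circles mark 15 genes by name, with IFIT1 at 7.29 and MMP9 at -7.29. Y-linked genes and XIST are not drawn.

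The 12 largest positive differences among genes above the level floor included 6 interferon-stimulated genes (ISGs) and the interferon-induced chemokine CXCL10. IFIT1, which binds viral RNA, had a log2 fold change of 7.29 (SE 0.78, adjusted p = 8.1e-18), and OAS1, a synthetase that senses double-stranded RNA, had 6.76 (SE 1.84, adjusted p = 0.0041) in the authors' deposited table. CXCL10 stood at 5.72, MX1 at 5.27, MX2 at 5.06, IFIT2 at 4.93 and OAS2 at 4.87 in the authors' deposited table. The remaining 5 were ALDH1A1, a retinaldehyde dehydrogenase (6.14, SE 0.50, adjusted p = 7.9e-31), the semaphorin SEMA3D (5.99), the chemokine CXCL12 (4.62, SE 0.36, adjusted p = 1.4e-34) and the transcription factors LHX9 (4.58) and ATOH8 (4.45) in the authors' deposited table. On the negative side the gelatinase MMP9 came first at -7.29 (SE 1.51, adjusted p = 5.5e-05) in the authors' deposited table, followed by the serpin SERPINB4 at -6.23. LCE3D, CRCT1 and KPRP, genes of the epidermal differentiation region, had -5.44, -5.37 and -4.86 in the authors' deposited table. The LCE genes have similar coding sequences, so the split of reads among them is uncertain. The neutrophil chemokine CXCL5 (-5.29, SE 0.41, adjusted p = 3.1e-34), the receptor TIE1 (-5.17), the decoy receptor IL13RA2 (-4.70, SE 0.28, adjusted p = 1.3e-59), the protease MMP10 (-4.69), the adenylyl cyclase ADCY8 (-4.67), the synuclein SNCB (-4.66) and the collagen COL10A1 (-4.64) completed the negative side in the authors' deposited table. Of these 24 genes, 7 had standard errors above 1 in the authors' deposited table: OAS1, CXCL10, SERPINB4, CRCT1 and ADCY8 no longer passed when the statistic was scaled to its own spread, while MMP9 and MX1 still did (adjusted p = 0.039 and 0.038).

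**Figure D2:**
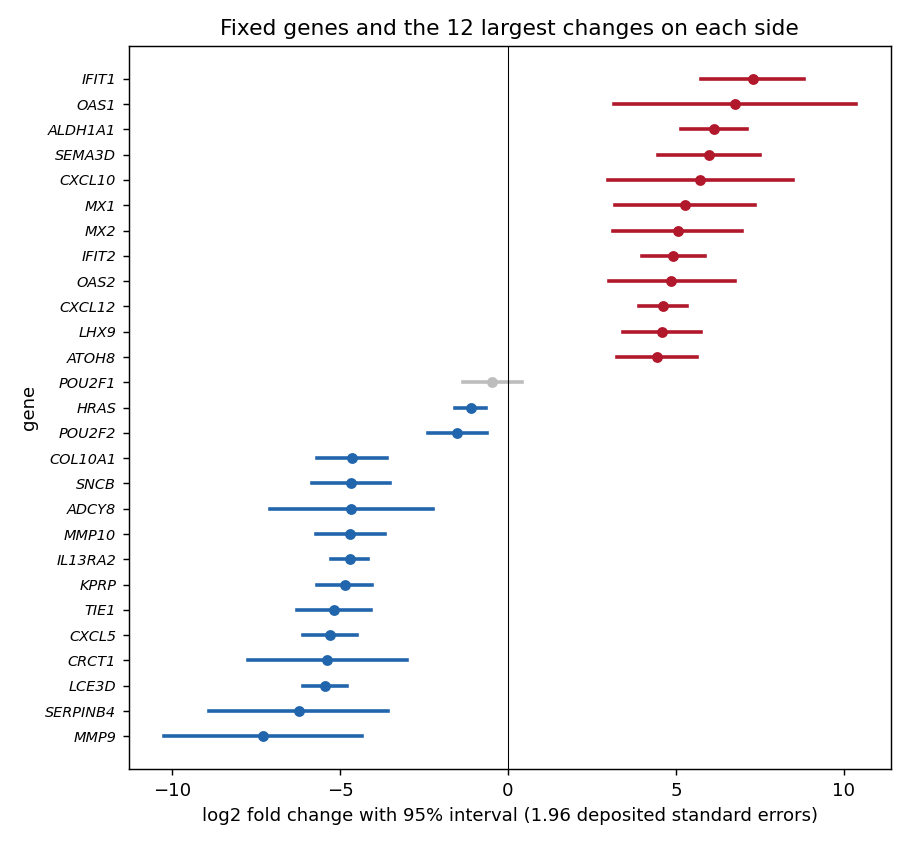
Log2 fold changes (points) with 95% intervals (lines, from the deposited standard errors) in the authors' deposited table for POU2F2, POU2F1, HRAS and the 12 largest positive and 12 largest negative differences. Red and blue mark genes that passed on the positive and negative side, and POU2F1, in grey, is the one whose interval spans 0.

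Cell cycle genes were higher in the numerator group. Of 34 genes of mitosis and the G2/M phases, 29 passed and all 29 were positive, with a median of 1.80 over the list in the authors' deposited table, and 32 passed when adjusted over the list alone (limma's camera, adjusted p = 9.44e-31). KIF20A, a kinesin of cytokinesis, had 3.08 (SE 0.36), the spindle gene ASPM 2.36, the kinetochore gene NDC80 2.35 and the mitotic transcription factor FOXM1 2.31 in the authors' deposited table. The 37 genes of DNA replication and the G1/S transition had 25 that passed, all positive, with a median of 1.18 in the authors' deposited table, and 30 when adjusted over the list alone (limma's camera, adjusted p = 9.76e-16). Cyclin E2 (CCNE2) had 3.16 (SE 0.71), the polymerase subunit POLE2 2.81, the replication factor MCM10 2.19 and thymidine kinase TK1 1.94 in the authors' deposited table. Among 10 nuclear lamina and high mobility group genes, 4 were positive and 1 negative of the 5 that passed in the authors' deposited table, and 7 and 2 when adjusted over the list alone (limma's camera, adjusted p = 0.00158). That group test was lost with fold changes in place of the score (adjusted p = 0.066). Lamin B1 (LMNB1), whose loss is a marker of senescence, had 2.71 (SE 0.43), HMGN2 1.44 and HMGB2 1.29, against -1.10 for HMGA1, in the authors' deposited table. Replication-dependent histones, of which 13 of 23 planned members were matched, moved the other way. Of the 13, 3 passed in the authors' deposited table, all negative, and 4 when adjusted over the list alone (limma's camera, adjusted p = 0.00197). H2AC18 had -1.75, H4C8 -0.86 and H2AC6 -0.73 in the authors' deposited table. The libraries were made from polyadenylated RNA, and most transcripts of these histone genes lack a poly(A) tail.

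The CDK inhibitors went both ways. CDKN2A, which encodes p16 and p14ARF, had -2.08 (SE 0.36, adjusted p = 9.0e-07) and its neighbour CDKN2B had -1.66 in the authors' deposited table, while CDKN2C had 2.44 and CDKN1B 0.72. With CDKN1A at -0.62, 5 of 7 passed in the authors' deposited table, 2 positive and 3 negative, with the same counts when adjusted over the list alone, and the list as a whole did not pass (limma's camera, adjusted p = 0.249). Of 26 p53 targets, 5 passed in the authors' deposited table, 1 positive and 4 negative (3 and 4 when adjusted over the list alone). The stress cytokine GDF15 had -1.74, the repair gene XPC -1.02 and the ribonucleotide reductase subunit RRM2B -0.88, against 1.12 for TP53I3, in the authors' deposited table. The p53 list did not pass (limma's camera, adjusted p = 0.781), and its median of 0.19 and mean of 0.03 in the authors' deposited table were positive while the test leaned negative.

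Genes of the senescence secretome were lower in the numerator group. Of 37 secretory factors, 20 passed, 16 of them negative, with a median of -1.27 in the authors' deposited table, and 23 negative and 4 positive passed when adjusted over the list alone (limma's camera, adjusted p = 1.25e-10). Besides CXCL5, IL1A had -4.09 (SE 0.31, adjusted p = 1.3e-36), CXCL8 had -3.39 (SE 0.90, adjusted p = 0.003, or 0.18 with the statistic scaled to its own spread) and IL1B had -3.38 (SE 0.51, adjusted p = 4.4e-09) in the authors' deposited table. The 4 positive members were IGFBP3 (2.87), CSF1 (2.05), TNFRSF11B (1.66) and IGFBP7 (1.51) in the authors' deposited table, named after their values were seen. IL6, the cytokine most often used as a readout of this secretome, had 0.61 and did not pass (SE 0.75, adjusted p = 0.74) in the authors' deposited table. Among 17 matrix metalloproteinases and their inhibitors, 7 were negative and 1 positive of the 8 that passed in the authors' deposited table, and 9 and 4 when adjusted over the list alone (limma's camera, adjusted p = 2.9e-09). Beside MMP9 and MMP10, stromelysin MMP3 had -3.84 (SE 0.31) and collagenase MMP1 had -3.58 (SE 0.29) in the authors' deposited table, and of the inhibitors TIMP1 had -1.85 and TIMP3, the positive member, 0.88. NF-kB feedback genes had 3 negative members that passed of 19 in the authors' deposited table, the adhesion molecule ICAM1 at -2.79, IER3 at -2.04 and NFKBIE at -1.37, and 4 when adjusted over the list alone. ICAM1 is also in the secretory list and IER3 in the RAS-ERK list. The NF-kB feedback list had a median of -0.26 in the authors' deposited table, and 16 members did not pass. As a group the NF-kB feedback genes lay just below the threshold (limma's camera, adjusted p = 0.0498). They did not lie below it with an inter-gene correlation of 0.05 (adjusted p = 0.14).

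Interferon-stimulated genes were higher in the numerator group, with 24 positive and 1 negative of 30 in the authors' deposited table and 27 and 1 when adjusted over the list alone (limma's camera, adjusted p = 7.99e-29). The list's median log2 fold change was 3.21 in the authors' deposited table, the highest of the 27 lists. CXCL11 had 5.37 and the negative member was the exonuclease ISG20 at -1.97 in the authors' deposited table.

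Transcriptional targets and feedback inhibitors of RAS-ERK signalling were lower in the numerator group, as HRAS was. Of 28 genes, 9 were negative and 1 positive in the authors' deposited table, and 10 and 1 when adjusted over the list alone (limma's camera, adjusted p = 4.19e-06). The ERK phosphatase DUSP6 had -2.68 (SE 0.44, adjusted p = 8.7e-08), the feedback inhibitor SPRY2 had -1.68, and DUSP2, at a mean of 18.9 normalized counts, had 1.92 in the authors' deposited table. AP-1 and ATF factors showed 1 gene that passed of 17, MAFF at -1.56 in the authors' deposited table, also 1 when adjusted over the list alone, and the list did not pass (limma's camera, adjusted p = 0.693). The AP-1 list had a median of -0.03 and a mean of 0.05 in the authors' deposited table, with a test that leaned negative. FOS (0.02, SE 1.40) and FOSB (-0.23, SE 1.67) were measured too imprecisely in the authors' deposited table to exclude several-fold differences in either direction.

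Matrix and contractile genes were higher in the numerator group. Of 34 collagen and matrix genes, 18 were positive and 2 negative in the authors' deposited table, and 20 and 2 when adjusted over the list alone (limma's camera, adjusted p = 5.32e-10). Elastin (ELN) had 4.33 (SE 0.87), COL3A1 had 3.31 (SE 0.74), COL4A1 had 3.27 (SE 0.49) and COL1A1 had 2.80 (SE 0.40) in the authors' deposited table, against -1.51 for DCN and -1.26 for COL7A1. All 13 of the 24 contractile and TGF-beta response genes that passed were positive in the authors' deposited table, and 15 positive and 2 negative passed when adjusted over the list alone (limma's camera, adjusted p = 1.7e-10). Calponin (CNN1) had 2.58, N-cadherin (CDH2) 2.39, ACTG2 2.22 and TAGLN 2.00 in the authors' deposited table. Fibroblast markers, which share COL1A1, COL1A2, COL3A1, DCN and LUM with the matrix list, had 6 positive and 4 negative of 17 in the authors' deposited table and 9 and 4 when adjusted over the list alone, with FBLN1 at 2.00 and COL1A2 at 1.70. Their group test (limma's camera, adjusted p = 0.0283) was lost with an inter-gene correlation of 0.05 (adjusted p = 0.095) and with ranks (adjusted p = 0.24).

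**Figure D3:**
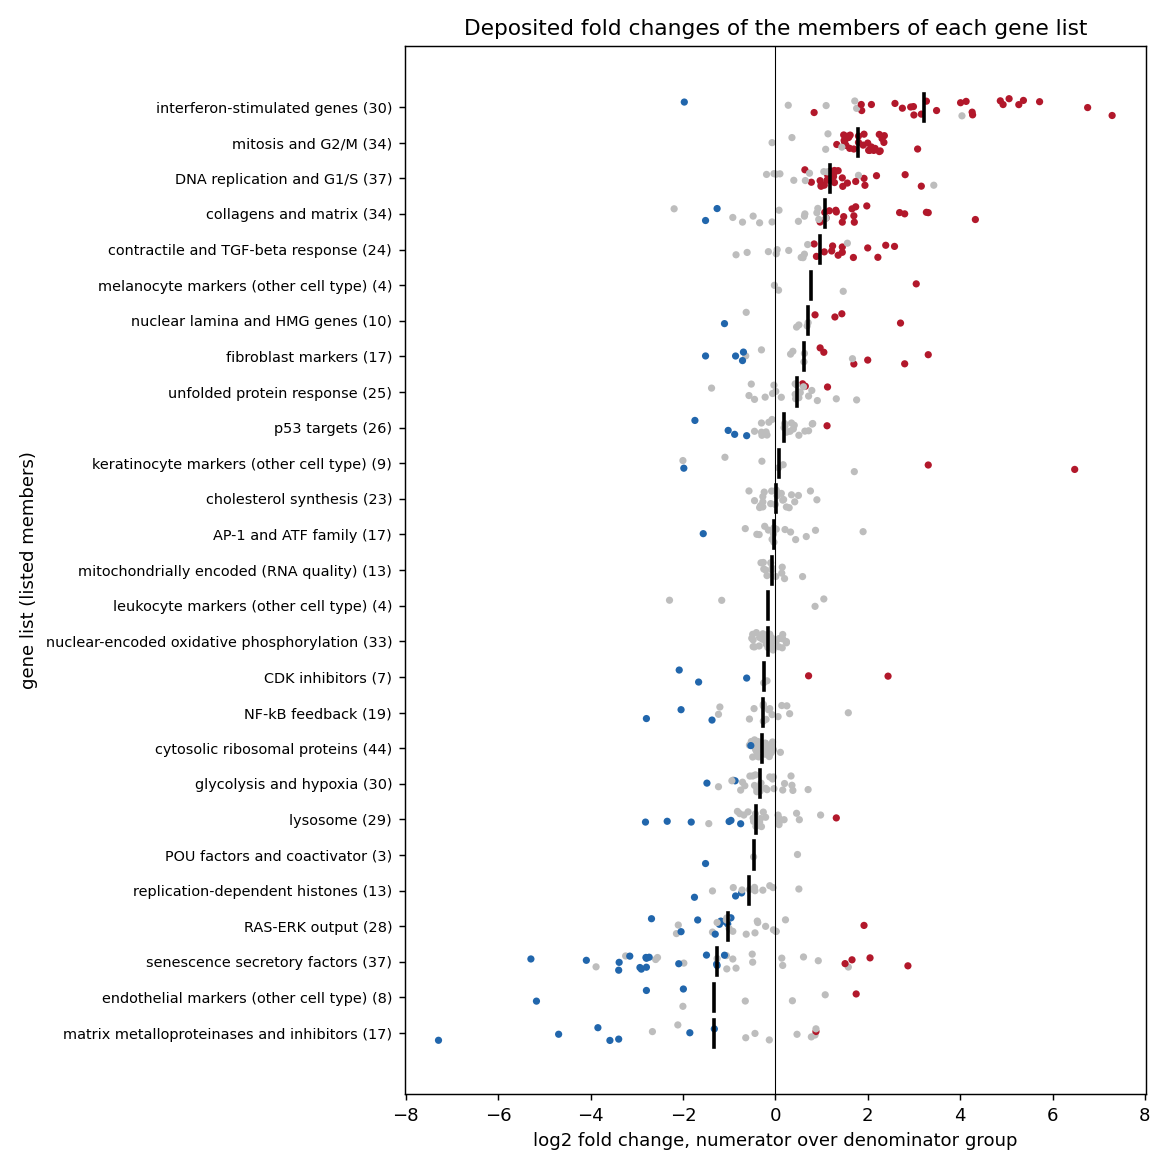
Log2 fold changes in the authors' deposited table of the members of 27 gene lists, with 1 point per gene, ordered by the list's median (black bar). Red and blue points passed on the positive and negative side and grey points did not, and the medians run from 3.21 for interferon-stimulated genes to -1.32 for endothelial markers and for matrix metalloproteinases and their inhibitors.

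Lysosomal genes had 6 negative members and 1 positive of 29 in the authors' deposited table and 9 and 3 when adjusted over the list alone (limma's camera, adjusted p = 0.00117). The cathepsins CTSS (-2.81), CTSK (-2.34, SE 0.28) and CTSL (-1.82) were lower, while the lipase LIPA had 1.32, in the authors' deposited table. Cytosolic ribosomal proteins had a median of -0.29 over 44 genes in the authors' deposited table and passed as a group on the negative side (limma's camera, adjusted p = 0.000319), but not with fold changes in place of the score (adjusted p = 0.066). RPS24 at -0.53 was the single one that passed in the authors' deposited table, and 0 passed when adjusted over the list alone. Processed pseudogenes of ribosomal genes were listed too, for example RPL4P4 with a mean of 15813 normalized counts beside 2392 for its parent RPL4 in the authors' deposited table, and how the counting divided reads between such pairs is not known. Glycolysis and hypoxia genes had 2 negative members that passed of 30, ENO2 at -1.48 and PFKFB3 at -0.87 in the authors' deposited table, also 2 when adjusted over the list alone. Their group test (limma's camera, adjusted p = 0.0287) was lost with an inter-gene correlation of 0.05 (adjusted p = 0.14). The unfolded protein response list had 3 positive members of 25, CRELD2 at 1.13, CALR at 0.65 and HSPA5 at 0.59 in the authors' deposited table, and 5 when adjusted over the list alone. Its group test (limma's camera, adjusted p = 0.0414) was lost with the same correlation (adjusted p = 0.14). Cholesterol synthesis had 0 of 23 members that passed in the authors' deposited table, and 0 when adjusted over the list alone, with 1 at an unadjusted p under 0.05 (limma's camera, adjusted p = 0.887). LSS stood at 0.18 (95% interval -0.40 to 0.77) and SREBF2 at -0.27 (-0.73 to 0.20) in the authors' deposited table. The list's median of 0.02 and mean of 0.05 in the authors' deposited table were positive, while the test leaned negative. Nuclear-encoded oxidative phosphorylation also had 0 of 33 in the authors' deposited table and 0 when adjusted over the list alone, with 4 at an unadjusted p under 0.05 (limma's camera, adjusted p = 0.0591), and UQCRC1 had -0.48 and ATP5F1B -0.13. Mitochondrially encoded genes, a check of RNA quality, had 0 of 13 in the authors' deposited table, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05 (limma's camera, adjusted p = 0.781), with COX1 at -0.10 and ND4 at -0.25.

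Markers of other cell types were mostly not listed or low. Of 18 keratinocyte markers 9 were listed and 3 passed in the authors' deposited table, among them KRT5 at 6.48 and KRT6A at 3.31 with means of 9.81 and 10.6 normalized counts. Adjusted over the list alone, 4 passed, 2 in each direction, and the group did not pass (limma's camera, adjusted p = 0.549), with a median of 0.07 and a mean of 0.71 in the authors' deposited table but a test that leaned negative. Endothelial markers had 8 listed of 14 in the authors' deposited table, 3 negative and 1 positive, with TIE1 at -5.17, ROBO4 at -2.79, ESAM at -1.99 and TEK at 1.75. Adjusted over the list alone 3 and 2 passed, and the group test (limma's camera, adjusted p = 0.0132) was lost with ranks (adjusted p = 0.27). Leukocyte markers had 4 listed of 18, 0 of which passed in the authors' deposited table, with LCP1 at -1.16 and CD14 at 0.86, and 1, CSF1R, at an unadjusted p under 0.05. Adjusted over the list alone 1 passed, a negative one (limma's camera, adjusted p = 0.671). Melanocyte markers had 4 listed of 10, with KIT at 3.05 (SE 0.46) the one that passed in the authors' deposited table, as when adjusted over the list alone (limma's camera, adjusted p = 0.0591).

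Among the list members named above as passing, these no longer passed when the statistic was scaled to its own spread over all genes: CCNE2, POLE2, XPC, RRM2B, CDKN2B, HMGB2, HMGA1, CXCL8, ICAM1, IER3, CXCL11, MAFF, SPRY2, COL3A1, PFKFB3, CTSL, LIPA, H2AC6, KRT5, TEK, TIMP1 and TNFRSF11B. A further set no longer passed in that setting and under the Benjamini-Yekutieli adjustment: TP53I3, CDKN1B, NFKBIE, DUSP2, ENO2, CRELD2, CALR, HSPA5, CTSS, RPS24, H4C8, KRT6A, ESAM, TIMP3, COL7A1, CDKN1A and ISG20. Their adjusted p in the first setting ran from 0.074 to 0.53.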

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

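All alternatives reported here were chosen after the data were seen. The alternatives chosen before the data were examined (other normalizations, tests and filters on counts, and leaving out each library) were not run, because no per-library column could be assigned to a sample. No paired analysis was possible because the columns carry no replicate numbers. Against 1865 genes (59.5% positive, 95% interval 57.2 to 61.7), 1081 passed under the Benjamini-Yekutieli adjustment (62.0% positive) and 489 under the empirical null (63.4% positive), and centring at the median log2 fold change gave 57.1% positive. Adjusting over the listed genes, filtering by level or removing pseudogenes left the count within 1.5 times. POU2F2, whose deposited -1.51 was not refitted, lost its call under Benjamini-Yekutieli (adjusted p = 0.094) and the empirical null (0.28). Of the other named genes, 17 lost their call under Benjamini-Yekutieli and 45 under the empirical null. That null takes its spread from the deposited statistic, whose robust SD was 1.49, and what widened it was not tested. No list changed direction past the threshold. The gene alternatives kept the deposited log2 fold changes or shifted them all by the median of 0.02. Named genes could therefore not change direction.

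Among lists, camera's adjusted p rose past 0.05 with a correlation of 0.05 for NF-kB feedback (0.14), glycolysis (0.14), the unfolded protein response (0.14) and fibroblast markers (0.095). With ranks it did so for fibroblast (0.24) and endothelial markers (0.27). With only genes above the level floor it did so for NF-kB feedback (0.08), the unfolded protein response (0.05) and endothelial markers (0.063). With fold changes in place of the score it did so for lamina and HMG genes (0.066), NF-kB feedback (0.054), glycolysis (0.066), the unfolded protein response (0.22) and ribosomal proteins (0.066). After the trend was removed it did so for NF-kB feedback (0.095) and glycolysis (0.15). Of the lists that had not passed, oxidative phosphorylation did with ranks (0.014), melanocyte markers with fold changes (0.044) and keratinocyte markers with genes above the level floor (0.02). The cause of these changes was not tested. The lists of mitosis, replication, secretory factors, metalloproteinases, interferon-stimulated genes, RAS-ERK output, matrix, contractile genes, lysosome and histones passed in all 5.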

Other observations

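The families, neighbours and copies below were tested after the data were seen, and the prediction for each weighed explanation was written before its test was run. Of 428 gene families, 21 passed camera at the preset inter-gene correlation of 0.01, and no stricter correlation was tried for them. Where members share reads, their correlation may exceed 0.01 and the p-values below may be too small. The late cornified envelope genes (LCE), structural proteins of the outer epidermis, stood first, with 11 of 13 listed members lower in the numerator group and a median log2 fold change of -4.09 (adjusted p = 7e-30) in the authors' deposited table. LCE1F had a mean of 8086 normalized counts and a log2 fold change of -4.56 in the authors' deposited table. Insulin-like growth factor binding proteins were higher, with 4 of 5 members passing (median 1.51, adjusted p = 6e-07) in the authors' deposited table. Keratins were higher too, 7 of 14 with a median of 1.65 (adjusted p = 0.00041), with KRT7 at 3.54 and KRT19 at 2.53 in the authors' deposited table. So the LCE genes and keratins that passed, both from epithelial families, lay on opposite sides. Among the keratins that did not pass were KRT10 (-0.29), KRT14 (1.71), KRT15 (-1.09) and KRT17 (0.17) in the authors' deposited table. The gamma protocadherins PCDHGA and PCDHGB had 4 positive members each of 12 and 7 listed (adjusted p = 0.028 and 0.021) in the authors' deposited table, and their transcripts share 3' exons, so the split of reads among them is uncertain. The PARP family had 6 positive of 12 (adjusted p = 0.013) in the authors' deposited table, among them PARP9 at 2.86 and PARP14 at 2.00, which are interferon-inducible, though PARP14 no longer passed under the empirical null (adjusted p = 0.18).

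A trend of the fold change with GC content, transcript length or mean level was weighed as the source of the differences in the interferon, mitosis and secretory lists. After that trend was removed over all genes, the median log2 fold change of the 30 interferon-stimulated genes was 3.21 (bootstrap 95% interval 2.46 to 4.34), that of the 34 mitosis genes 1.61 (1.5 to 1.94) and that of the 37 secretory factors -1.24 (-2.59 to -0.82), computed from the authors' deposited table. All 3 stayed beyond the bounds set before the test was run (1, 0.5 and -0.5), which argues against the trend as the whole source. Before removal the medians were 3.21, 1.80 and -1.27, and their directions were known when the bounds were set. The bootstrap resampled genes as if independent, so its intervals may be too narrow. The construct, the day and the level of the introduced HRAS stay open and were not tested, since the groups are unnamed and HRAS itself differed. Library batch stays open for the same reason.

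Genes that lay next to each other and both passed tended to share their sign. Among 355 neighbouring protein-coding pairs, 71.8% had the same sign in the authors' deposited table, against 46.0 to 59.1% in 95% of 10000 permutations. Sharing of reads or function within gene families was weighed as the explanation. With pairs of the same symbol root set aside, 66.4% of 292 pairs still had the same sign against 45.9 to 59.1% (permutation p = 0.0001, the smallest these permutations can give), so family membership as read from symbols does not account for the whole pattern. Runs of at least 4 consecutive listed protein-coding genes that all passed with the same sign numbered 12, against a median of 0 and a highest value of 5 in permutations, and included CRCT1 to LCE2C (6 genes) and KPRP to SMCP (7 genes) on the negative side and LIPA to IFIT5 (5 genes) on the positive side. Most of the runs were made up largely of a single family, such as GBP, LCE, IFIT, MMP, KRT, CXCL or PCDHG genes. Related genes with unlike symbols, such as CRCT1 and KPRP beside the LCE genes, may still contribute, and shared regulation of a region was not tested.

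Fold changes of processed pseudogenes followed those of their parent genes. Across 944 pairs of a pseudogene and the parent named in its symbol, the log2 fold changes in the authors' deposited table correlated with Pearson r = 0.61 and Spearman rho = 0.60 (permutation p = 1e-05 for Pearson's r, the smallest that 100000 permutations can give), and r was 0.60 without the 2 pairs whose parents lay farthest from the median. Pairs are genes, not independent replicates, and some share a parent. This is consistent with reads of the parent being counted on its copy, as an aligner that does not split reads across introns could do, and 184 of the copies had a higher mean than the parent. Processed pseudogenes held 5.0% of the summed means in the authors' deposited table, and 55 pseudogenes of these pairs passed, 16 of them with a parent that passed too, all 16 with the parent's sign. Transcription of the copies themselves was not tested.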
